A study of Mus musculus with 12 samples.

How the data were processed

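Gene expression was measured in mouse embryonic stem (ES) cells and in their progeny during differentiation towards cardiomyocytes, on the Affymetrix Mouse Exon 1.0 ST array, which carries several probe sets along each gene. Per the labels' protocols, cells were differentiated in a DMEM-based medium with 10% serum, RNA was extracted with TRIzol and depleted of ribosomal RNA, and the amplified cDNA was labelled with biotin. The labels name 3 stages: undifferentiated ES cells at day 0, embryonic bodies at day 7 and cardiac bodies at day 14, with 2 replicates each. They do not say whether the 2 replicates of a stage came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Each of the 6 samples has a gene-level and an exon-level profile, which makes 12 entries. The 2 profiles of a sample come from 1 array as far as their labels go. Over 14677 genes, each exon-level profile correlated best with the gene-level profile of the same label (r across genes of the deviations from each gene's mean over the samples from 0.954 to 0.975, against at most 0.746 for any other).

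The deposited values are log2 signals. They were made with RMA in Affymetrix Power Tools, per the submitters' processing notes, and the versions are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises probes, and whether the normalization was by quantiles is not given in the sources used here. Per the labels, the core probe sets defined on mm9 were summarised to 23332 transcript clusters in the gene-level table and 229581 probe sets in the exon-level table. The medians of the gene-level samples lay between 6.47 and 6.79 on the log2 scale and those of the exon-level samples between 7.11 and 7.42. Neither table gives detection calls, so no row was set aside as background. A log2 array signal has a floor and a ceiling, so changes from or to low levels may be understated, and the number of arrays limits the precision. Positions of the probe sets are not used here.

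Symbols came from the platform annotation and were updated through a mouse gene table of assembly GRCm38.p6. At the gene level, 14996 rows had 1 symbol, 1019 had several and 7317 had none, and 27 symbols were updated. At the exon level these numbers were 209279, 4446 and 15856, with 24312 symbols updated and 208810 rows matched. Rows with several symbols were tested and counted but not named. This leaves some list members, among them Myh6 and Myh7, without a gene-level row of their own. The mean of their exon-level probe sets is given instead where it is named as such, a choice made after the data were seen.

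Gene levels were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) on the values as deposited, with all 6 samples in 1 fit so that the 3 stages share an estimate of the spread. A cluster was called at a Benjamini-Hochberg adjusted p under 0.05. The 3 comparisons share samples. For 25 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 compared each list with all other genes, with 1 cluster per gene (the one with the highest mean) and at least 5 measured members. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members move one way on balance, without reference to other genes. The counts of members that rose or fell come from the test over all clusters.

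Exon usage was measured as the log2 signal of a probe set minus the median of all probe sets of its gene in the same sample, and compared in the same way. Genes needed 4 or more probe sets and a median at or above the 50th percentile of all exon-level values in both stages. Probe sets needed a mean at or above the 25th percentile in at least 1 of the stages. A probe set was counted at an adjusted p under 0.05 and a difference of 1 or more. A further list of known alternatively spliced genes was also adjusted over the list alone.

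The tests were run on simulated data with the spread of these samples. For day 7 against day 0 the gene-level test, over 23332 rows, recovered 2.94% of simulated log2 changes of 1, 75.8% of changes of 2 and 100% of changes of 4, with 2 false calls. Only 68, 66 and 66 rows were changed, against 2481 clusters called in the data. The adjustment was therefore stricter than in the data, and the shares recovered may be too low. The exon usage test, over 95498 probe sets, recovered 0%, 4.55% and 92.4%, with 1 false call. limma's diffSplice recovered 29.4%, 90.9% and 100% but made 325 false calls, of which 316 lay in genes without a simulated change. Its counts are therefore given as an alternative and its probe sets are not named. The simulation gave each probe set its own estimated spread. In the data diffSplice called 189 probe sets at day 14 against day 0 and 179 against day 7. Both are fewer than the 325, so its false calls may be overstated here.

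Genes were named by a rule fixed before the data were examined. Per comparison it took the 10 largest rises and the 10 largest falls among called genes with 1 symbol whose samples did not overlap, and the 3 called members of each list with the largest change. Predicted genes and olfactory or vomeronasal receptors were not named. Other genes named are said to be chosen after their values were seen, as were Pou5f1, Nanog, Esrrb, Nkx2-5 and H19 in the plot of levels by day. Alternatives fixed in advance were a replicate block, each sample left out, quantile normalization, centring on sample medians, fits of the compared stages alone, robust moderation with a trend, filters on dim rows, a gene summary from the exon-level table, other gene references and limits for exon usage, and other list tests. The alternative for linear values was not needed, since the tables hold log2 values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.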

Results

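Transcript levels were measured on exon arrays in 6 samples of mouse cells: undifferentiated ES cells (day 0), embryonic bodies (day 7) and cardiac bodies (day 14), with 2 samples per stage. Embryonic bodies are aggregates in which ES cells begin to form the germ layers. The series was made to study gene expression and alternative splicing during cardiomyocyte differentiation. Gene-level profiles of a stage correlated across clusters at 0.974 (day 0), 0.978 (day 7) and 0.973 (day 14), and those of different stages at 0.929 to 0.958. The median absolute difference between the 2 samples of a stage was 0.256, 0.227 and 0.286 on the log2 scale. Changes below are log2 differences ± the standard error of the limma fit, with n = 2 per stage, and levels are log2 means ± SD.

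The first comparison asked what changed between ES cells and embryonic bodies. At day 7 the genes of the pluripotent state had fallen: 24 of 28 measured members of the pluripotency list fell and none rose, with a median change of -2.64 (camera adjusted p = 1.19e-17; adjusted p = 0.245 with an estimated correlation). Nr0b1, a nuclear receptor of the ES cell network, fell by 4.17 ± 0.25 (limma adjusted p = 0.00265), Dnmt3l, a cofactor of DNA methylation, by 4.07 ± 0.26 and Zfp42, a classical ES cell marker, by 4.07 ± 0.24. The largest falls also took in genes known from germ cells, Hormad1 (-5.23 ± 0.20) and Morc1 (-4.31 ± 0.27), and the histone gene H2ac1 (-4.75 ± 0.27). Septin1, Lrrc2, Laptm5, Liph and Tgm1 fell by between 4.13 and 4.36.

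The largest rise at day 7 was that of Acta2, smooth muscle actin, from 5.67 ± 0.31 to 12.47 ± 0.63 (adjusted p = 0.00265). Cdh11, a mesenchymal cadherin, rose by 6.28 ± 0.48, the growth factor binding protein Igfbp5 by 6.08 ± 0.53, the secreted Wnt antagonist Frzb by 5.64 ± 0.28, and Has2, which makes hyaluronan, by 5.56 ± 0.39. Nrp1, Hsd11b2 and Pcdh7 rose by 5.21 to 5.60. Of the smooth muscle list, 7 of 15 rose (adjusted p = 2.53e-05; 0.245 as the adjusted p with an estimated correlation), with Cald1 at 3.11 ± 0.35 and Tagln at 2.60 ± 0.47. Of 23 cardiac transcription factors, 10 rose and none fell (median 1.71, adjusted p = 4.43e-07; adjusted p = 0.304 with an estimated correlation), led by Hey2 (3.60 ± 0.48), Tbx20 (3.56 ± 0.72) and Mef2c (3.18 ± 0.41). The replicates of day 7 differed by over 1 in 9 of these 23 genes, among them Tbx20 (11.59 and 9.59).

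Markers of other lineages moved too. In the endothelium list 9 of 23 rose and 1 fell (median 0.704, adjusted p = 0.000522; adjusted p = 0.516 with an estimated correlation). Cdh5, the endothelial cadherin, rose by 4.63 ± 0.31, and Kdr, a VEGF receptor, by 3.30 ± 0.32. The endothelial members were lower in replicate 1 of day 7 than in replicate 2 by a median of 0.849. In the epithelial list 6 of 16 rose (median 0.588, adjusted p = 0.000522; adjusted p = 0.304 with an estimated correlation), with the keratin Krt18 at 4.65 ± 0.23 and the tight junction gene Cldn6 at 2.67 ± 0.20. Of the fibroblast and extracellular matrix list 7 of 27 rose and 1 fell (adjusted p = 3.64e-05; adjusted p = 0.375 with an estimated correlation), with Postn, a matrix protein, at 4.47 ± 0.75. Its members were higher in replicate 1 of day 7 by a median of 0.425. Blood genes differed more between these replicates, by a median of 0.914, and 2 of 17 rose at day 7, Lmo2 (2.34 ± 0.21) and Runx1 (1.85 ± 0.25), while 2 fell (adjusted p = 0.0214; adjusted p = 0.516 with an estimated correlation). In the endoderm list, where replicate 1 was higher by a median of 0.565, 3 of 21 rose and 1 fell (median 0.218, or 0.128 with samples centred on their medians; adjusted p = 0.0268; adjusted p = 0.603 with an estimated correlation). Cyp26a1, which breaks down retinoic acid, rose by 3.19 ± 0.62 and Sox17 by 2.17 ± 0.34, and the transferrin gene Trf fell by 2.00 ± 0.23.

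Imprinted genes rose, 10 of 17 against 1 that fell (median 2.42, adjusted p = 5.77e-07; adjusted p = 0.304 with an estimated correlation). Igf2, a fetal growth factor, rose by 5.82 ± 0.18, Plagl1 by 3.63 ± 0.29 and Asb4 by 4.01 ± 0.56. Airn, the long noncoding RNA antisense to Igf2r, rose by 5.74 ± 0.36, and its other transcript cluster by 2.46. The labels do not say whether strand was kept. The signalling list had 9 of 36 risen and 1 fallen (adjusted p = 0.000601; adjusted p = 0.245 with an estimated correlation), with Tgfb2 at 4.85 ± 0.41 and Bmp5 at 4.72 ± 0.39. In 14 of its 36 members, and in 5 of the 17 imprinted genes, the replicates of day 7 differed by over 1. The cell cycle list went down, with 5 of 35 fallen and 1 risen (median -0.442, adjusted p = 0.00517; adjusted p = 0.516 with an estimated correlation): Ccne1, a G1 cyclin, fell by 2.13 ± 0.26 and the cell cycle inhibitor Cdkn1a rose by 1.91 ± 0.27. In the glycolysis list 3 of 13 fell (median -0.537, adjusted p = 0.0172; adjusted p = 0.516 with an estimated correlation), among them the phosphofructokinase Pfkp by 3.55 ± 0.23. The samples of day 0 stood apart in this list, with 12 of 13 members higher in replicate 1, by a median of 0.391. In the macrophage and leukocyte list 3 of 17 fell and none rose (median -0.159, or -0.249 with samples centred on their medians; adjusted p = 0.0268; adjusted p = 0.304 with an estimated correlation), Laptm5, Cd68 and Coro1a. In the sarcomere list 5 of 23 rose already (median 0.126, or 0.0351 with samples centred on their medians; adjusted p = 0.0108; adjusted p = 0.516 with an estimated correlation), among them Tpm1 by 2.72 ± 0.20 and Tnni1 by 2.37 ± 0.32.

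Adjusted over the list alone, 25 pluripotency, 5 glycolysis and 4 macrophage genes fell and 14 cardiac transcription factors, 7 smooth muscle, 8 epithelial and 5 sarcomere genes rose. On the same basis, 11 endothelial genes rose and 2 fell, as did 11 and 1 of the matrix list, 2 and 2 of blood, 5 and 1 of endoderm, 12 and 2 imprinted, 10 and 1 signalling, and 1 and 6 cell cycle genes. Over all 23332 clusters, 1249 were higher and 1232 lower at day 7, and 1092 and 972 of these changed by at least 1. Leaving out any of the samples lowered these counts: they ranged from 317 higher without replicate 1 of day 0 to 900 without either sample of day 14, and from 248 lower without replicate 2 of day 0 to 870. Centring each sample on its median moved the median change of all clusters from -0.0229 to -0.113 and gave 1168 higher and 1630 lower, so that 41.7% of calls were higher instead of 50.3%; quantile normalization gave 1283 and 1395. No named gene changed direction under centring, which shifts all changes of a comparison by the same small amount.

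**Figure D1:**
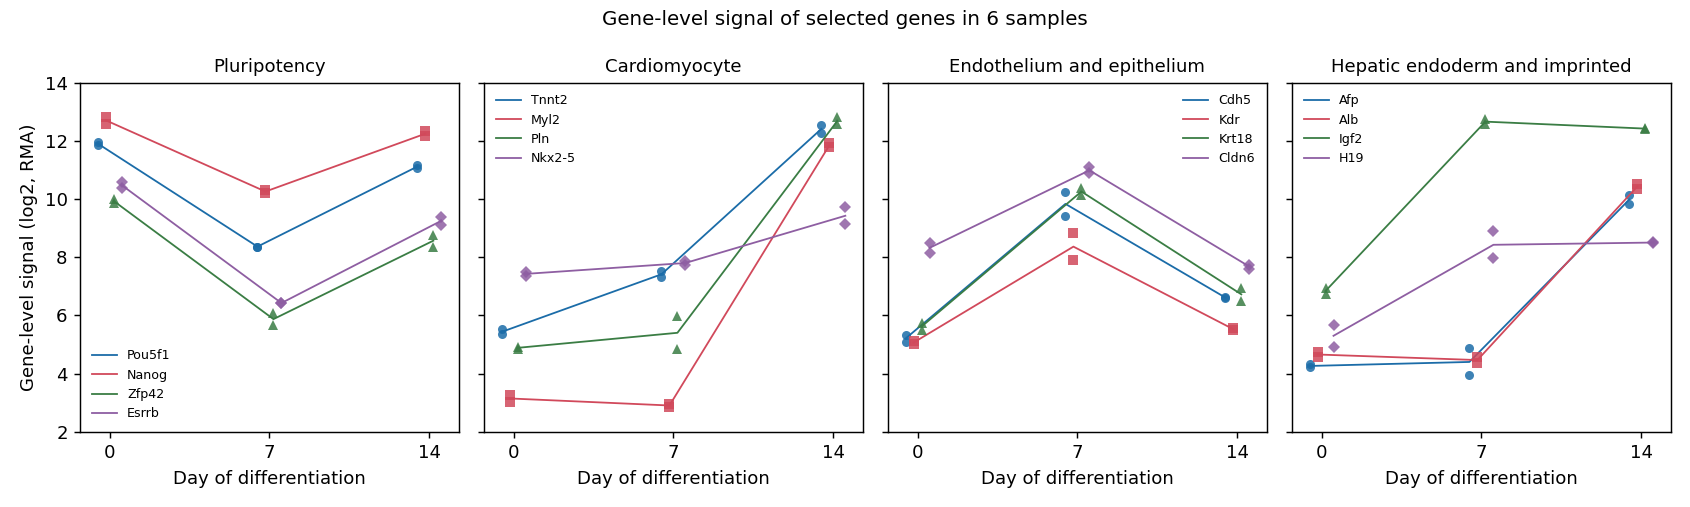
Gene-level log2 RMA signal (vertical axis) of 16 genes in 4 panels against the day of differentiation (horizontal axis); each point is 1 of the 2 samples of a stage, shifted sideways by gene, and the lines join the stage means. Pou5f1, Nanog, Zfp42 and Esrrb are lowest at day 7, Myl2, Alb and Afp are high at day 14 alone, and Cdh5, Kdr, Krt18 and Cldn6 are highest at day 7.

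The second comparison set cardiac bodies against ES cells. At day 14 the contractile apparatus of the heart was strongly raised: 20 of 23 measured sarcomere genes rose and none fell, with a median of 4.67 (camera adjusted p = 1.59e-32; adjusted p = 0.0964 with an estimated correlation). Myl2, the regulatory light chain of ventricular myosin, rose from 3.14 ± 0.17 to 11.85 ± 0.10, a change of 8.71 ± 0.18 (adjusted p = 0.00035). Tnnt2, cardiac troponin T, rose by 6.99 ± 0.19, Tnnc1, troponin C, by 6.17 ± 0.31 and the stress-responsive sarcomere gene Ankrd1 by 7.36 ± 0.36. Of genes without a gene-level row of their own, the means of the exon-level probe sets rose by 8.12 ± 0.59 for Actc1, cardiac actin, and by 4.93 ± 0.24 for Myl4, the atrial light chain. Those of the myosin heavy chains Myh6 and Myh7 rose by 6.51 ± 0.28 and 5.74 ± 0.53. Myh6 and Myh7 are near-identical copies, so their separate values are uncertain.

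Genes of cardiac excitation and energy supply rose with them. Of the calcium handling and ion channel list 17 of 31 rose and none fell (median 1.72, adjusted p = 2.2e-19; adjusted p = 0.0964 with an estimated correlation). Pln, phospholamban, the inhibitor of the calcium pump of the sarcoplasmic reticulum, rose by 7.80 ± 0.38, the potassium channel gene Kcnj5 by 6.30 ± 0.53 and the sodium-calcium exchanger gene Slc8a1 by 4.83 ± 0.28. In the list of cardiomyocyte metabolism and secreted factors 11 of 16 rose (median 3.53, adjusted p = 1.01e-17; adjusted p = 0.0964 with an estimated correlation), with Popdc2 at 6.06 ± 0.31 and the muscle cytochrome oxidase subunits Cox8b and Cox6a2 at 5.38 ± 0.41 and 4.88 ± 0.26. Cardiac transcription factors rose in 13 of 23 cases (median 2.00, adjusted p = 2.28e-15; adjusted p = 0.0964 with an estimated correlation), led by Tbx5 (5.30 ± 0.54), Tbx20 (5.01 ± 0.72) and Myocd (4.72 ± 0.22). Of the fatty acid oxidation list 4 of 19 rose (adjusted p = 1.5e-06; adjusted p = 0.0964 with an estimated correlation), with Ppargc1a, a regulator of mitochondrial genes, at 5.47 ± 0.24. Sorbs2 and Tecrl rose by 6.57 ± 0.43 and 6.24 ± 0.18. Sarcomere genes were higher in replicate 1 of day 14 than in replicate 2 by a median of 0.446. So were cardiac transcription factors, by 0.423, and metabolic and secreted factors, by 0.465.

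Alb, albumin, rose by 5.79 ± 0.19 and Afp, alpha-fetoprotein, by 5.73 ± 0.33, both products of fetal liver and yolk sac, and Fgb, a fibrinogen chain, by 3.61 ± 0.58. In all, 6 of 21 members of the endoderm list rose and none fell (adjusted p = 2.79e-06; adjusted p = 0.341 with an estimated correlation). Of the smooth muscle list 3 of 15 rose (adjusted p = 1.43e-06; adjusted p = 0.0964 with an estimated correlation), Acta2 by 7.13 ± 0.34, Nexn by 3.13 ± 0.24 and Cnn2 by 1.76 ± 0.30. Imprinted genes rose in 8 of 17 cases (adjusted p = 7.88e-07; adjusted p = 0.255 with an estimated correlation), Igf2 by 5.59 ± 0.18. The signalling list had 5 of 36 risen (median 0.109, or -0.0219 with samples centred on their medians; adjusted p = 0.0267; adjusted p = 0.231 with an estimated correlation), and the matrix list 2 of 27, Col6a1 and Fstl1 (median 0.388, or 0.257 with samples centred on their medians; adjusted p = 0.017; adjusted p = 0.528 with an estimated correlation).

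Pluripotency genes were lower at day 14 than at day 0, with a median of -0.618: 5 of 28 fell (adjusted p = 8.38e-08; adjusted p = 0.255 with an estimated correlation), among them Tcl1 by 2.12 ± 0.24, Klf5 by 1.49 ± 0.20 and Zfp42 by 1.37 ± 0.24. The largest falls were those of the membrane protein gene Emp1 (-3.81 ± 0.35), the small GTPase gene Mras (-3.04 ± 0.29) and the transglutaminase gene Tgm1 (-2.92 ± 0.22). Socs3, an inhibitor of cytokine signalling, fell by 2.40 ± 0.21, where its other cluster changed by -1.17, and Ly75, Hal, Pcolce2, Liph, Urah and Hmces by 2.32 to 2.69. The cell cycle list lay lower (median -0.458, adjusted p = 3.49e-06; adjusted p = 0.341 with an estimated correlation) though 1 member, Cdkn1a, passed the test and had risen. Its members differed between the samples of day 14 too, replicate 1 minus replicate 2 having a median of -0.305 (7 of 35 higher). The epithelial list also lay lower (median -0.284, adjusted p = 0.0137; adjusted p = 0.267 with an estimated correlation), with Spint1 the member that fell.

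Adjusted over the list alone, 21 sarcomere, 22 calcium handling and channel, 14 metabolic and secreted, 17 transcription factor, 11 fatty acid oxidation, 9 smooth muscle and 9 endoderm genes rose. So did 10 imprinted genes, with 1 fallen, 7 signalling genes, 3 of the matrix list, with 1 fallen, 1 epithelial gene, with 3 fallen, and 1 cell cycle gene, with 9 fallen, while 11 pluripotency genes fell. At day 14 against day 0, 614 clusters were higher and 160 lower, so 79.3% of calls were higher. With samples centred on their medians, which moved the median change of all clusters from -0.0272 to -0.158, they were 510 and 276, or 64.9% higher. Leaving out any 1 of the samples lowered the counts, to 138 higher without replicate 1 of day 0 to 475 without either sample of day 7, and 11 lower without replicate 2 of day 0 to 70.

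The third comparison set day 14 against day 7. Sarcomere genes rose in 19 of 23 cases (median 4.28, camera adjusted p = 8.74e-25; adjusted p = 0.146 with an estimated correlation), with Myl2 at 8.95 ± 0.18, Myl7, the atrial light chain 2 gene, at 5.79 ± 0.29 and Actn2, alpha-actinin of the Z disc, at 5.63 ± 0.23. Calcium handling and ion channel genes rose in 15 of 31 cases (adjusted p = 1.49e-14; adjusted p = 0.146 with an estimated correlation) and metabolic and secreted factors in 11 of 16 (adjusted p = 5.35e-15; adjusted p = 0.143 with an estimated correlation), with Pln at 7.29 ± 0.38 and Cox6a2 at 5.29 ± 0.26. Mlip and Myoz2, both known from striated muscle, rose by 6.02 ± 0.32 and 5.39 ± 0.28. Of the cardiac transcription factors 6 of 23 rose (median 0.57, adjusted p = 0.0249; adjusted p = 0.472 with an estimated correlation), with Tbx5 at 4.11 ± 0.54, Smyd1 at 4.06 ± 0.31 and Irx4, a ventricular factor, at 3.69 ± 0.28. The 2 samples of day 14 stood apart in this list, with 20 of 23 members higher in replicate 1, by a median of 0.423. Fatty acid oxidation genes rose in 7 of 19 cases (median 1.12, adjusted p = 9.65e-11; adjusted p = 0.115 with an estimated correlation): Ppargc1a by 5.16 ± 0.24, Cpt1a, which admits fatty acids to mitochondria, by 3.53 ± 0.20 and Lpl by 2.84 ± 0.27. At day 7, 3 of these 19 had fallen against day 0 and none had risen (list adjusted p = 0.232): Cpt1a by 3.52 ± 0.20, Acadm by 1.40 ± 0.16 and Pdk4 by 1.02 ± 0.22. At day 14 none of the 3 was called against day 0, with Cpt1a at 0.0085, Acadm at -0.287 and Pdk4 at 0.991.

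Pluripotency genes rose in the same interval, 17 of 28 with none fallen and a median of 1.80 (adjusted p = 1.73e-17; adjusted p = 0.146 with an estimated correlation). Dppa2 rose by 4.46 ± 0.66, Dnmt3l by 3.85 ± 0.26 and Nr0b1 by 3.52 ± 0.25. Nr0b1 went from 12.15 ± 0.03 at day 0 to 7.98 ± 0.47 at day 7 and 11.51 ± 0.03 at day 14. Endothelial genes fell in 4 of 23 cases (median -1.26, adjusted p = 2.69e-07; adjusted p = 0.32 with an estimated correlation), among them Cdh5 by 3.22 ± 0.31, Flt1 by 2.96 ± 0.28 and Kdr by 2.84 ± 0.32. Epithelial genes fell in 5 of 16 cases (median -0.956, adjusted p = 2.41e-12; adjusted p = 0.115 with an estimated correlation), with Krt18 at -3.54 ± 0.23, Krt19 at -3.44 ± 0.38 and Cldn6 at -3.31 ± 0.20. The largest falls were those of Hsd11b2 (-4.55 ± 0.40), Frzb (-4.39 ± 0.28) and Gimap4 (-3.95 ± 0.32), and Has2 fell by 3.94 ± 0.39. Blood genes (median -0.692, adjusted p = 0.0032; adjusted p = 0.472 with an estimated correlation) held 1 fall, Lmo2, and 1 rise, Spi1. Matrix genes lay lower (adjusted p = 0.00116; adjusted p = 0.467 with an estimated correlation), with Pdgfrb the member that fell, by 2.83 ± 0.34. The replicates of day 7 differed in the cardiac transcription factor, endothelium, blood, matrix, signalling and imprinted lists as given for the first comparison.

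Alb (5.98 ± 0.19), Afp (5.59 ± 0.33) and Trf (4.01 ± 0.23) rose between day 7 and day 14, 3 of 6 risen members of an endoderm list that did not pass the list test (adjusted p = 0.243). The signalling list went down (median -0.222, adjusted p = 0.00828; adjusted p = 0.15 with an estimated correlation), where Shh fell by 1.83 ± 0.32 and Fgf1 rose by 2.60 ± 0.32. The imprinted list also went down (adjusted p = 0.0125; adjusted p = 0.472 with an estimated correlation), with Peg3 fallen by 1.81 ± 0.24. The skeletal muscle list passed with a median of 0.242 and no called member (adjusted p = 0.0198; adjusted p = 0.32 with an estimated correlation). Adjusted over the list alone, 23 pluripotency, 19 sarcomere, 22 calcium handling and channel, 15 metabolic and secreted, 14 fatty acid oxidation and 4 skeletal muscle genes rose and 13 epithelial and 2 imprinted genes fell. On the same basis, 7 cardiac transcription factors rose and 2 fell, as did 3 and 12 endothelial, 1 and 2 blood, 2 and 5 matrix and 3 and 8 signalling genes. Of all clusters 493 were higher and 237 lower, or 457 and 285 with samples centred on their medians. Leaving out any 1 of the samples lowered the counts, to 116 higher without replicate 1 of day 14 to 238 without either sample of day 0, and 10 lower without replicate 1 of day 14 to 90 without replicate 1 of day 7.

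**Figure D2:**
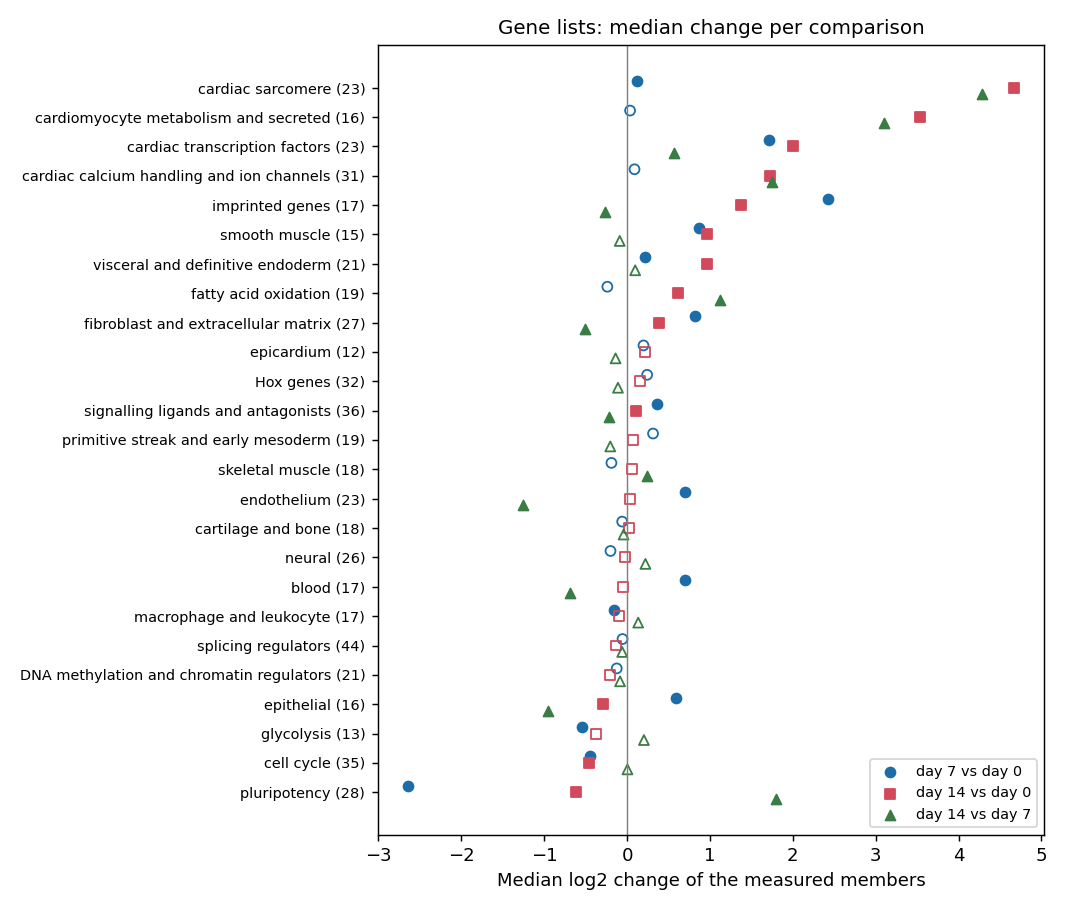
Median log2 change of the measured members of 25 gene lists (horizontal axis; number of members in brackets) in 3 comparisons; filled symbols mark lists with a camera adjusted p under 0.05 and open symbols the others. Sarcomere genes stand at 4.67 for day 14 against day 0, and pluripotency genes at -2.64 for day 7 against day 0 and at 1.80 for day 14 against day 7.

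Across the 3 comparisons 14, 13 and 13 of the 25 lists passed camera with the preset correlation. With an estimated correlation none passed, the lowest adjusted p being 0.245, 0.0964 and 0.115. This version also rests on the few residual degrees of freedom of these samples. Failing it therefore does not show that correlation between members undid the list results. At day 7 the signalling and smooth muscle lists went to a camera adjusted p of 0.245. Their estimated correlations, -0.0102 and 0.0134, lay near or below the preset 0.01. Fry called 13, 12 and 10 lists, of which 9, 11 and 9 were also called by camera. Lists of the primitive streak, cartilage and bone, neural, epicardium, Hox, DNA methylation and chromatin, and splicing regulator genes passed camera in none of the 3 comparisons. Among splicing regulators, 44 of which were measured, 5 rose and 1 fell at day 7. The largest of these changes was the fall of Celf4, by 1.96 ± 0.30. Ptbp2 rose by 1.73 ± 0.29 at day 7, Celf2 by 2.25 ± 0.29 at day 14 against day 0 (its other cluster changed by 0.969), and Rbfox1, a muscle and neural splicing factor, by 1.59 ± 0.20 at day 14 against day 7.

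Exon usage was compared between the same stages, which addresses the splicing question of the series. Over 95498, 99106 and 100843 probe sets, limma's test of the relative signal called 0 in each of the 3 comparisons, with lowest adjusted p of 0.147, 0.226 and 0.171. At an unadjusted p under 0.05 there were 7896, 5593 and 4826. Without any change, a share of about 0.05 of the probe sets tested would reach this by chance. The count at day 14 against day 7 lay below that share, and the other counts above it. diffSplice called 393, 189 and 179, but it also made many false calls on simulated data. On data simulated for day 7 against day 0, the main test recovered 0% of differences of 1, 4.55% of differences of 2 and 92.4% of differences of 4, and sizes in between were not simulated.

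In the list of known alternatively spliced genes, 1283, 1247 and 1537 probe sets of 52, 51 and 62 genes were tested. Adjusted over the list alone, 2, 9 and 15 probe sets passed, against 0 over all probe sets tested. Those that passed lay in 2, 4 and 8 genes. Their genes were chosen after their values were seen. In Tpm1, a tropomyosin with alternative muscle exons, probe set 4599174 rose relative to its gene by 3.07 ± 0.21 at day 7 (adjusted p over the list alone = 0.023) and by 3.17 at day 14 against day 0. Its own signal at day 0 was 4.73, below the lower quartiles of the exon-level day 0 samples (5.24 and 5.36). The gene median rose by 3.43 at day 7. Some other Tpm1 probe sets also moved towards the gene median by day 7, 4415283 from above and 4404559 from below, and others did not. A floor or ceiling of the signal was not told apart from a change in exon usage here. Probe sets 4866752 and 4425421 of Tpm1 changed relative to the gene by -2.98 and -2.67 at day 14 against day 7. The gene median rests on the middle probe sets, and 4425421 was among these in both samples of day 7. Its relative spread there may therefore be understated. In Atp2a2, the calcium pump of the sarcoplasmic reticulum, probe set 4740804 rose relative to its gene by 2.27 at day 14 against day 0 and by 2.12 against day 7. Probe set 4845684 of Tacc2 fell by 2.10 ± 0.17 relative to its gene at day 7. Further probe sets passed in Tnnt2, Ablim1, Svil, Sorbs2, Pdlim5 and Smarcd3. With the replicate number as a block the counts were 0, 4 and 6, so neither probe set called at day 7 passed. Leaving out any 1 of the samples lowered the 2, 9 and 15 to 0 to 1, 1 to 5 and 0 to 3 probe sets. In the first comparison 1 passed without replicate 2 of day 0 and 0 when any other sample was left out. In the second 1 passed when replicate 1 of day 0 or either sample of day 7 was left out, and in the third 0 passed when either sample of day 7 or of day 14 was.

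**Figure D3:**
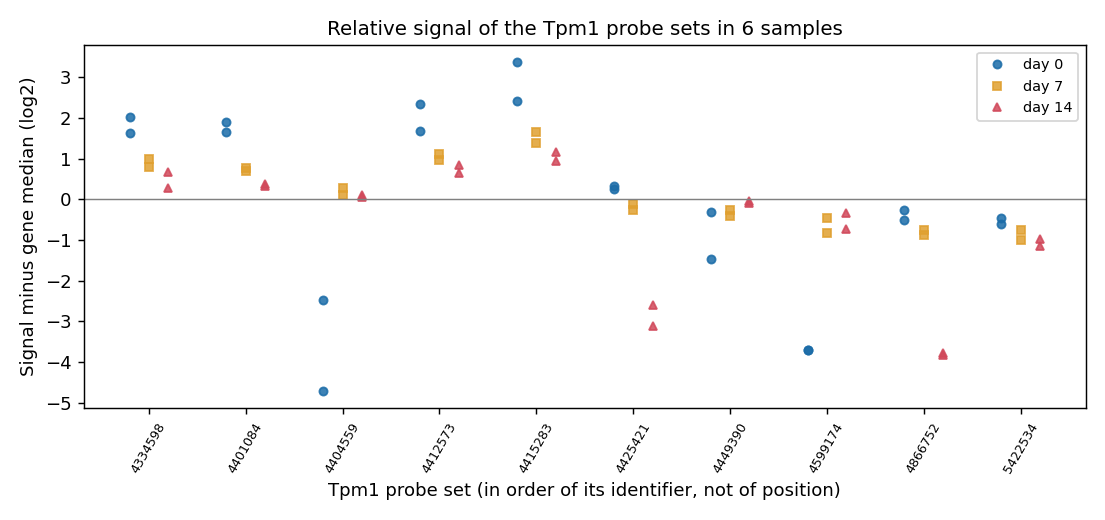
Signal of each of the 10 tested Tpm1 probe sets minus the median of the gene's probe sets in the same sample (vertical axis, log2), by probe set identifier (horizontal axis); each point is 1 of 2 samples of day 0, day 7 or day 14. Probe set 4599174 lies near -3.7 at day 0 in both samples and above -1 afterwards, and 4866752 and 4425421 are lowest at day 14.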

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

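All tests and comparisons in this part were chosen after the results were seen. Genes were set apart where their change from day 7 to day 14 differed from that from day 0 to day 7. In total, 229 clusters fell by day 7 and then rose, and 213 rose and then fell, by their calls in the 2 comparisons. Over all 23332 clusters, whether so called or not, a limma test of the second minus the first interval called 987 positive and 849 negative. Rises in both intervals were seen for 25 clusters and falls in both for 0, where independent lists would share 26.4 and 12.5. Both intervals share the day 7 samples, so opposite calls are favoured: 100 simulations without any change gave 0 such clusters, and independent lists of these sizes would share 26.0 and 12.7. The simulations hold no effects and the independent lists no shared samples, so the excess over either does not measure a shared effect. Of the 229, 25 were still called lower at day 14 than at day 0 (median of all 229, -0.351), and of the 213, 37 were still called higher (median 0.427).

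Among the gene lists, camera on the difference between the intervals (second minus first) passed for 15. The median difference was 4.39 for pluripotency, 3.59 for the sarcomere, 3.38 for cardiomyocyte metabolism and secreted factors, 1.55 for fatty acid oxidation, 1.45 for calcium handling and ion channels, 0.967 for glycolysis, 0.461 for skeletal muscle and 0.36 for macrophages and leukocytes. It was -2.70 for imprinted genes, -1.76 for endothelium, -1.64 for epithelial genes, -1.41 for fibroblasts and matrix, -1.39 for blood, -0.562 for signalling genes and -0.528 for smooth muscle. With an estimated correlation no list passed, the lowest adjusted p being 0.18.

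Pluripotency genes returned at day 14, with 25 of 28 above day 7 in both samples. An exchange of samples between stages would not leave both sets of genes in the same samples, and 20 of 23 sarcomere genes were above all other samples in both samples of day 14. Cells like those of day 0 mixed into the day 14 samples were not decided: against them as the whole source, and with signal taken as proportional to the transcript, which was not tested, the 19 listed genes that had fallen by 2 or more at day 7 stood at a median of 60.9% of day 0 at day 14, while 180 of 248 other such clusters lay below that median, 72 of them by a one-sided limma test, and Emp1, Mras and Tgm1 stood at 7.12%, 12.2% and 13.3%. In the direction that mixing would give, pluripotency genes were lower in replicate 1 of day 14 than in replicate 2 (median -0.239, 4 of 28 higher) and sarcomere genes higher (0.446, 20 of 23). However, pluripotency genes were lower in replicate 1 of day 0 too (-0.121, 8 of 28 higher) and these are single samples. The median of all clusters was also lower in replicate 1, at 6.58 against 6.79 at day 14 and 6.47 against 6.63 at day 0. The pluripotency differences cannot be told from this offset of the whole sample. The unmatched comparison came first and had been read as excluding such cells. After it was seen it was replaced by sets of the other genes matched on day 0 signal. Of 10000 such sets, 4.21% had a median as high as the listed genes (-0.716). This lies between limits of 1% and 5%, also written after the values were seen. Differentiating cells may express the matched genes too, so this median cannot decide the question. Such cells and pluripotency expression in differentiating cells stay open.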

How the results depend on the processing

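The alternatives for the known spliced genes, and the use of exon-level means for genes without a row of their own, were chosen after seeing the data; the other alternatives were planned. None of the 197 named gene results reversed under any setting, and 89 were called under all settings that gave them a value. With the replicate block, 182 kept their call, and with robust moderation 196. Most settings could not have reversed a result. The block, the compared stages alone, robust moderation, the filters and the limit on the change leave the estimated change as it is. The largest rises and falls had been chosen for samples that did not overlap, so leaving out 1 sample could not turn them. The absence of reversals is therefore little evidence of stability. Gene counts that moved by over 1.5 times were the following. Brackets give what a setting changed, and no cause was tested. At day 14 against day 0, lower calls were 276 after centring, 70 with the compared stages alone (fewer samples), and 280 and 346 with filters at the 25th and 50th percentile (fewer clusters tested); exon-level means gave 1017 higher and 376 lower. At day 14 against day 7, the compared stages alone gave 238 higher and 72 lower, the filters 366 and 431 lower, and exon-level means 961 higher and 470 lower. An estimated correlation left 0 lists in each comparison. Exon usage went from 0 to 8 probe sets at day 7 with robust moderation and a trend, and to 393, 189 and 179 with diffSplice.

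Known spliced probe sets, at 2, 9 and 15, were 0, 1 and 3 with the compared stages alone, 1, 0 and 7 in genes that changed by less than 1, and 11, 15 and 35 with diffSplice. The setting of genes that changed by less than 1 left out many of them. Of the 2, 9 and 15, 1, 8 and 7 lay in genes whose median rose by 1 or more. At day 14 against day 0 they were 14 with robust moderation, 3 with the gene-level table as reference, 126 with limits at the 25th and 0th percentile and 4 at a difference of 2 or more. At day 14 against day 7 the last 3 settings gave 23, 62 and 7. Leaving out single samples gave 317 to 900 higher and 248 to 870 lower at day 7, 138 to 475 and 11 to 70 at day 14 against day 0, and 116 to 238 and 10 to 90 against day 7. It gave 12 to 17, 11 to 14 and 11 to 16 lists, 0 exon usage calls, and 0 to 1, 1 to 5 and 0 to 3 known spliced probe sets. The lone sample left in a stage was assumed to vary like the others; leaving out a sample of the third stage equals fitting the compared stages alone.

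Samples share replicate numbers, but the numbers were not taken as paired, since the labels state no design and no batch. Deviations from the stage means of samples with the same number correlated at 0.486 for days 0 and 14. They correlated at 0.0826 for days 0 and 7 and 0.0913 for days 7 and 14. Samples of days 0 and 14 with the same number may therefore share a source of variation that the labels do not name. With the replicate block, clusters higher and lower were 1437 and 1403, 549 and 133, and 425 and 214, and known spliced probe sets 0, 4 and 6. The tables used give no detection calls, which limits what can be said of dim rows.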

Other observations

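Several genes without a gene-level row of their own had a level at day 7 unlike those of days 0 and 14, by the means of their exon-level probe sets; they were chosen after their values were seen. The keratin gene Krt8 stood at 8.56 ± 0.02, 12.17 ± 0.21 and 8.79 ± 0.40 (log2 mean ± SD, n = 2) at days 0, 7 and 14, and the imprinted gene Nnat at 8.10 ± 0.27, 11.42 ± 0.59 and 8.11 ± 0.02. The Wnt antagonist gene Dkk1 rose by 3.78 ± 0.33 at day 7 and fell by 2.73 ± 0.33 afterwards. T (brachyury), a marker of early mesoderm, rose by 1.66 ± 0.22 and fell by 1.30 ± 0.22. The neural tubulin gene Tubb3 fell by 1.85 ± 0.20 and rose by 1.72 ± 0.20.

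The 2 samples of day 7 differed in whole groups of genes. Of 32 measured Hox genes, 31 were higher in replicate 1, by a median of 0.711, against 22 at day 0 and 19 at day 14. The embryonic globin gene Hbb-bh1 stood at 7.02 ± 2.69 at day 7 in the mean of its probe sets, with SDs of 0.178 at day 0 and 0.0674 at day 14. These are differences between single samples and were not tested.

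Of the 26 results for known spliced probe sets that passed over the list alone, 18 were lower relative to their gene and 5 had an own signal that moved against the gene median (limma, adjusted over the 26). Of the other 13 that were relatively lower, the own signal rose in 4 by that test and changed in neither direction past it in 9. Of the 5, the own signal of probe set 4845684 of Tacc2 changed by -2.004 at day 7 while the gene's median changed by 0.0993, and that of 5287495 of Ablim1 by -2.51 at day 14 against day 7 with a gene median change of 0.23. The own signal of 4866752 and 4425421 of Tpm1 changed by -2.32 and -2.02 in that interval, with a gene median change of 0.657. The remaining 1 was 4845684 of Tacc2 at day 14 against day 0, at -1.20 with a gene median change of 0.211. The probe sets had been selected for their change relative to the gene, so these values are a description and no explanation was tested.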
